A study of Mus musculus with 4 samples.

How the data were processed

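Gene expression was measured on Affymetrix mouse arrays in 4 RNA samples, 1 array per group. The groups were control and Snai1 knockout embryoid bodies on day 5, and control and Snai1 knockout teratomas at week 6. Controls carry the genotype F/F in the labels. Per the labels' protocols, embryoid body RNA was purified on columns and teratoma RNA was extracted with Trizol, and 250 ng of total RNA per sample was amplified and labelled with biotin.

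The authors deposited log2 expression values per probe set. Per the submitters' processing notes, the values were made with the affy package and RMA, a method that corrects background, normalizes arrays by quantiles and summarises probes. Versions, the chip definition and whether all 4 arrays were normalized together are not given in the sources used here. Scanner files were not used here, so the authors' background correction and normalization could not be repeated.

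The deposited table held 45101 probe sets, of which 64 were control probe sets. Of the 45037 others, 34945 named 1 gene in the array platform's annotation, 932 named several and 9160 had no gene in the annotation used here. The Entrez numbers of 34741 of the 1-gene probe sets matched a RefSeq gene table (assembly GRCm38.p6), and 0 symbols changed. Each of the 18193 genes took the probe set with the highest mean over the 4 arrays. Probe sets that name several genes were left out, and no genome position is given because the annotation's build is not named.

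RMA log2 values have no true zero, so each array was given a floor at the median of its own non-control probe sets. A value below the floor was set to the floor before differences were taken. Where 1 of the 2 arrays lay below its floor, the difference is a bound and is written as at least that many fold. No fold is given where both arrays lay below the floor. A gene was counted as higher or lower at an absolute log2 difference of 1 or more, which is 2-fold. With 1 array per group there is no spread between replicates, so no test was run and no p-value is given. The only internal measure of spread is the difference between probe sets of the same gene, which shares the RNA and the array and leaves out variation between cultures or tumours.

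In total 43 gene lists for cell types, lineages, signalling targets and tissue states were fixed before the data were examined, together with the comparisons, the floor and the rule for naming genes. For 4 list members the symbol was updated through synonyms. A list's value is the median log2 difference over members at or above the floor on at least 1 of the 2 arrays, with bounds entered at their bound. Its percentile is taken among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays only. Lists share members, for example 8 of the 11 Nodal and activin targets on the array are also in another list, so their medians are not independent. The two-cell-like list had 0 of 4 members above the floor and the X-inactivation list had 1 of 2, so neither has a median. List genes that no probe set used here names were not analysed here.

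Genes are named by 5 parts of the rule. The Snail family is given on every array. In each tissue, the 8 genes with the largest positive and the 8 with the largest negative difference are named among genes at or above the floor on both arrays. The 6 highest and 6 lowest bounds are named in alphabetical order. Up to 4 members with the largest absolute difference may be named for each list. For genes that differ at least 2-fold in both tissues, the 6 with the largest smaller difference are named for the same direction and for opposite directions. Genes with clone, Rik, Gm or accession names were counted and not named. Any other gene is said to have been chosen after its values were seen.

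Agreement between tissues was described with Pearson and Spearman correlations across genes, which are not independent replicates, and with the overlap that independent lists would give. Alternatives covered the probe set per gene, the scaling, the floor, the fold threshold, the random lists and the mean in place of the median. Probe sets called shared-sequence here are those with the suffix _x_at, _s_at or _a_at. Whether the shared sequence is that of another gene or of other transcripts of the same gene was not checked. The pipeline was tested on simulated data. For a simulated change of 1.5 or 3.0 log2 units in 100 genes each, it called 100% in both tissues, with 0 unchanged genes called. Measured genes numbered 12146 for embryoid bodies and 11979 for teratomas. The simulated noise had an SD of 0.2, and the changed genes were chosen well above the floor. Real probe sets of the same gene differed more, with a pooled SD of 0.31 in embryoid bodies and 0.29 in teratomas. The simulation therefore checks the code and gives no rate of false calls on the real arrays. A further 400 lists were drawn at random from all measured genes, changed ones included. Of these, 7.0% fell outside the central 95% of random lists in the embryoid body simulation and 5.75% in the teratoma simulation. Such lists do not stand for real lists, whose genes can vary together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 for loess and matplotlib 3.10.9. Each array's signal limits what can be seen: genes below the floor on both arrays have no difference, and the number of arrays limits the precision of every value.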

Results

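Transcript levels were measured in 2 differentiation settings of mouse embryonic stem cells with and without Snai1, a zinc-finger repressor best known for switching off epithelial genes during epithelial-mesenchymal transition and gastrulation. Embryoid bodies, which are stem cell aggregates that differentiate without added direction, were sampled on day 5. Teratomas, which are tumours of mixed tissues, grew from stem cells placed under the skin of the hind limb of male nude mice aged 6 weeks and were sampled at week 6. Each of the 4 groups, control and knockout in each setting, had 1 array, so there are no replicates and no difference given here has a replicate check. Log2 values covered 45037 non-control probe sets and 18193 genes. The floor was 4.71 on the control embryoid body array, 4.73 on the knockout embryoid body array, 5.08 on the control teratoma array and 5.04 on the knockout teratoma array. Arrays of the same tissue correlated at 0.982 for embryoid bodies and 0.985 for teratomas across probe sets, and arrays of different tissues at 0.864 to 0.880. The 3' minus 5' signal of Gapdh, which reports on RNA integrity and labelling, was 0.17 and 0.10 in control and knockout embryoid bodies and 0.65 and 0.40 in control and knockout teratomas.

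The Snail family was read first, because it bears on the labels. Snai1 has 1 probe set, which read 4.78 in control embryoid bodies, just above the floor, and 3.45 in knockout embryoid bodies, below it. In teratomas it lay below the floor on both arrays, at 3.59 in the control and 3.44 in the knockout. Whether this probe set lies in the deleted part of the gene is not given, so it checks the labels weakly. Snai2, a close relative that also drives mesenchymal change, was 2.86-fold lower in knockout embryoid bodies (9.07 against 10.59) and 2.43-fold lower in the knockout teratoma (7.15 against 8.43). Its other probe set differed by -1.40 in embryoid bodies. In teratomas that probe set lay below the floor in the knockout, with a bound of -0.24, so the 2-fold difference there rests on a shared-sequence probe set. Snai3 differed by 0.34 in embryoid bodies and lay below the floor in both teratomas.

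The first comparison asked which genes and lineages differ in day 5 embryoid bodies that lack Snai1. The medians of the mesenchymal, primitive blood, endothelial, visceral endoderm and Hox lists lay below the central 95% of random lists. Those of the epithelial, definitive endoderm, epiblast, Nodal target and FGF target lists lay above it. The collagen-binding proteoglycan gene Lum was 82.3-fold lower, the matrix gene Postn 61.6-fold lower and the fibrillar collagen gene Col3a1 55.1-fold lower, while the endodermal migration receptor Cxcr4 was 5.15-fold higher. Of 12282 measured genes, 268 were at least 2-fold higher and 489 at least 2-fold lower, and at 8-fold the counts were 0 higher and 42 lower. Among 2-fold genes with another measured probe set, the other probe sets all had the same sign for 84 of 87 higher and 183 of 205 lower genes, with a pooled SD between probe sets of 0.31.

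Mesenchymal genes had a median difference of -1.13 over 33 measured members, at percentile 0 of random lists, and 17 were lower against 2 higher. Besides Lum, Postn and Col3a1, the fibrillar collagen gene Col5a2 was 30.4-fold lower, at 5.03 against 9.95. The transcription factor gene Foxc1 went the other way, 4.86-fold higher. The fibroblast list, 8 of whose 15 members on the array are also in the mesenchymal list, had a median of -1.61, with 9 of 14 measured members lower, including the proteoglycan gene Dcn at 5.17 against 9.58. Vim, the mesenchymal filament gene, was chosen after its values were seen and differed by -0.54. Imprinted genes had a median of -0.46, with 5 of 22 lower and 1 higher. Among them Plagl1 differed by -2.80 and Dlk1 by -2.15, although another Dlk1 probe set differed by -0.13.

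Primitive blood genes formed the lowest list, with a median of -1.97 and 8 of 11 members lower. Embryonic globins Hba-x and Hbb-y were 20.8-fold and 12.8-fold lower, from 13.51 to 9.13 and from 13.25 to 9.57. The erythroid regulators Klf1 and Nfe2 lay below the floor in the knockout only, at least 13.0-fold and at least 18.2-fold lower. Adult red cell genes had a median of -0.61, at percentile 0.41, with 2 of 6 measured members lower and 2 others above 0. The heme synthesis gene Alas2 was 17.1-fold lower and the membrane transporter gene Slc4a1 at least 16.4-fold lower. The platelet chemokine gene Pf4 was 25.8-fold lower and the platelet gene Plek at least 15.5-fold lower. Endothelial genes had a median of -0.80, with 6 of 18 lower and 1 higher. The junction gene Cldn5 differed by -2.87, the receptor genes Tek and Tie1 by -2.45 and -1.76, and the cadherin gene Cdh5 by -1.62.

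Heart and lateral mesoderm genes had a median of -0.52, with 8 of 19 lower and 2 higher. Cardiac actin Actc1 differed by -2.34, the transcription factor genes Foxf1 and Hand1 by -2.31 and -1.87, and cardiac myosin Myh6 was at least 4.78-fold lower. Hox genes, which pattern the trunk, had a median of -1.13, with 7 of 14 measured members lower and 0 higher. Hoxc8 was at least 15.5-fold lower, Hoxc10 at least 4.77-fold, Hoxb6 at least 4.11-fold, and Hoxb4 3.79-fold, with another Hoxb4 probe set at -0.29. The mesothelial gene Upk3b was at least 13.7-fold lower.

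Visceral and parietal endoderm genes, which mark extraembryonic endoderm, had a median of -0.81, with 11 of 28 lower and 1 higher. Alpha-fetoprotein, Afp, was lower at 5.20 against 9.84, Apom was 15.2-fold lower, the retinol carrier gene Rbp4 9.19-fold and Apoc2 at least 9.05-fold lower. Lgals2, a galectin gene, was 30.2-fold lower. Definitive endoderm genes went the other way, with a median of 1.10 and 7 of 14 higher against 1 lower. Cxcr4 differed by 2.37, the hormone precursor gene Trh by 2.22 and the organizer genes Lhx1 and Gsc by 2.10 and at least 2.08. Gsc was above the floor only in the knockout, at 6.79, and is also a member of the Nodal and the primitive streak lists.

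Nodal and activin targets had a median of 1.06, with 6 of 11 higher and 0 lower. Fgf8 differed by 2.09, Eomes by 1.72 and the secreted inhibitor gene Cer1 by 1.65. FGF and ERK targets had a median of 0.84 with all 12 measured members above 0. Of these, 4 were at least 2-fold higher: Dusp6 at 1.68, Spry1 at 1.34, Dusp4 at 1.09 and Spry4 at 1.02, although another Spry4 probe set differed by 0.037. Epiblast genes had a median of 0.44, with 6 of 13 higher and 0 lower. Fgf5 was 4.51-fold higher, the head transcription factor gene Otx2 4.46-fold, Zic2 2.58-fold and Nodal 2.37-fold. The epithelial list had a median of 0.70, with 7 of 33 higher and 0 lower. Tight junction genes Cldn4 and Marveld3 differed by 1.92 and 1.47, the anchoring filament gene Lad1 by 1.34 and the transcription factor gene Elf3 by 1.33. E-cadherin, Cdh1, was chosen after its values were seen, as a gene that Snai1 is known to repress, and differed by 0.86.

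Primitive streak genes split, with 7 of 15 higher and 4 lower around a median of 0.48, above the central 95% of random lists. Fgf8, Lhx1 and Gsc were higher and Foxf1 lower. The list no longer stood apart with the floor at the 25th percentile (median 0.045) or the 65th (median 0.17), or with none. Wnt targets had a median of 0.43 (Lgr5 1.73, Ascl2 1.66, Sp5 1.65 and Dkk1 1.47), with other Ascl2 probe sets down to 0.14, and trophoblast genes a median of 0.41 (Gata3 1.30 but Cdx2 -1.70). Without a floor, Wnt targets stood at percentile 96.1 and trophoblast genes at 90.5. Neural progenitor genes had a median of 0.43, led by Dll3 at 1.58 and Sox3 at 1.16, and neuronal genes one of 0.23, just above the central 95% of random lists but at percentile 93.0 without a floor.

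Stress and growth lists differed little in size, although their medians lay above the central 95% of random lists. The immediate early list stood at percentile 100 and the p53 and hypoxia lists at 99.9. Medians were 0.36 for immediate early and heat shock genes (Junb 1.32, Ier2 1.31), 0.29 for p53 targets (Trp53i11 0.99), 0.22 for hypoxia and glycolysis genes (Pfkl 0.89) and 0.13 for proliferation genes (Aurkb 0.55, with another probe set at -0.09). The last stood at percentile 97.9 and at 95.5 after quantile normalization. Naive and general pluripotency genes had a median of 0.17, at percentile 97.0, with 2 of 24 higher and 2 lower. Within them Eras and Klf5 differed by 1.64 and 1.43, and Tfcp2l1 and Klf4 by -1.65 and -1.31.

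The other lists lay within the central 95% of random lists in embryoid bodies. Their medians were -0.02 for skeletal muscle, -0.12 for cartilage and bone, -0.08 for gut epithelium, -0.02 for airway epithelium, -0.07 for exocrine pancreas and 0.16 for astrocytes and oligodendrocytes. They were -0.10 for neural crest, -0.24 for eye, 0.02 for epidermis, 0.06 for germ cells, -0.09 for BMP targets and -0.03 for interferon-stimulated genes. Host leukocyte genes had -0.14, lymphocyte genes 0.06, adipose genes -0.24, Y-linked genes 0.12 and ribosomal protein genes 0.02. The sign of the epidermis, lymphocyte and ribosomal medians turned under some scalings, and mean and median had opposite signs for the airway, eye and ribosomal lists. Single members still differed by over 2-fold, such as the goblet cell gene Tff3 at -4.11 and the interferon-stimulated gene Rsad2 at -2.52.

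Among genes outside the lists that were measured on both arrays, the largest higher values were those of Tph1, a serotonin synthesis enzyme gene, at 2.91, the inner ear matrix gene Coch at 2.60, Eya4 at 2.59 and the retinoic acid hydroxylase gene Cyp26a1 at 2.54. Pax1 differed by 2.38 with another probe set at 0.28, and Irx5 by 2.29. Genes above the floor only in the knockout, inside or outside the lists, included Alx1 at least 5.84-fold, Cobl at least 3.19-fold, Lrrc4 at least 2.77-fold, Olfm4 at least 2.78-fold and Tafa2 at least 4.24-fold higher. With the floor at the 65th percentile, the counts were 169 higher and 310 lower, and Tie1, Hoxb6, Hoxc10, Myh6, Gsc, Ascl2, Cobl and Tafa2 were under 2-fold. Lrrc4, Olfm4 and Spry4 lay below that floor on both arrays. With the mean of probe sets, Tfcp2l1 differed by -0.42, and Klf5, Eya4, Cdh5, Lgr5, Marveld3, Sox3, Myh6, Spry4, Alx1, Cobl and Lrrc4 were under 2-fold, while without shared-sequence probe sets Klf5 lay below the floor on both arrays and Ascl2 and Dlk1 were under 2-fold.

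**Figure D1:**
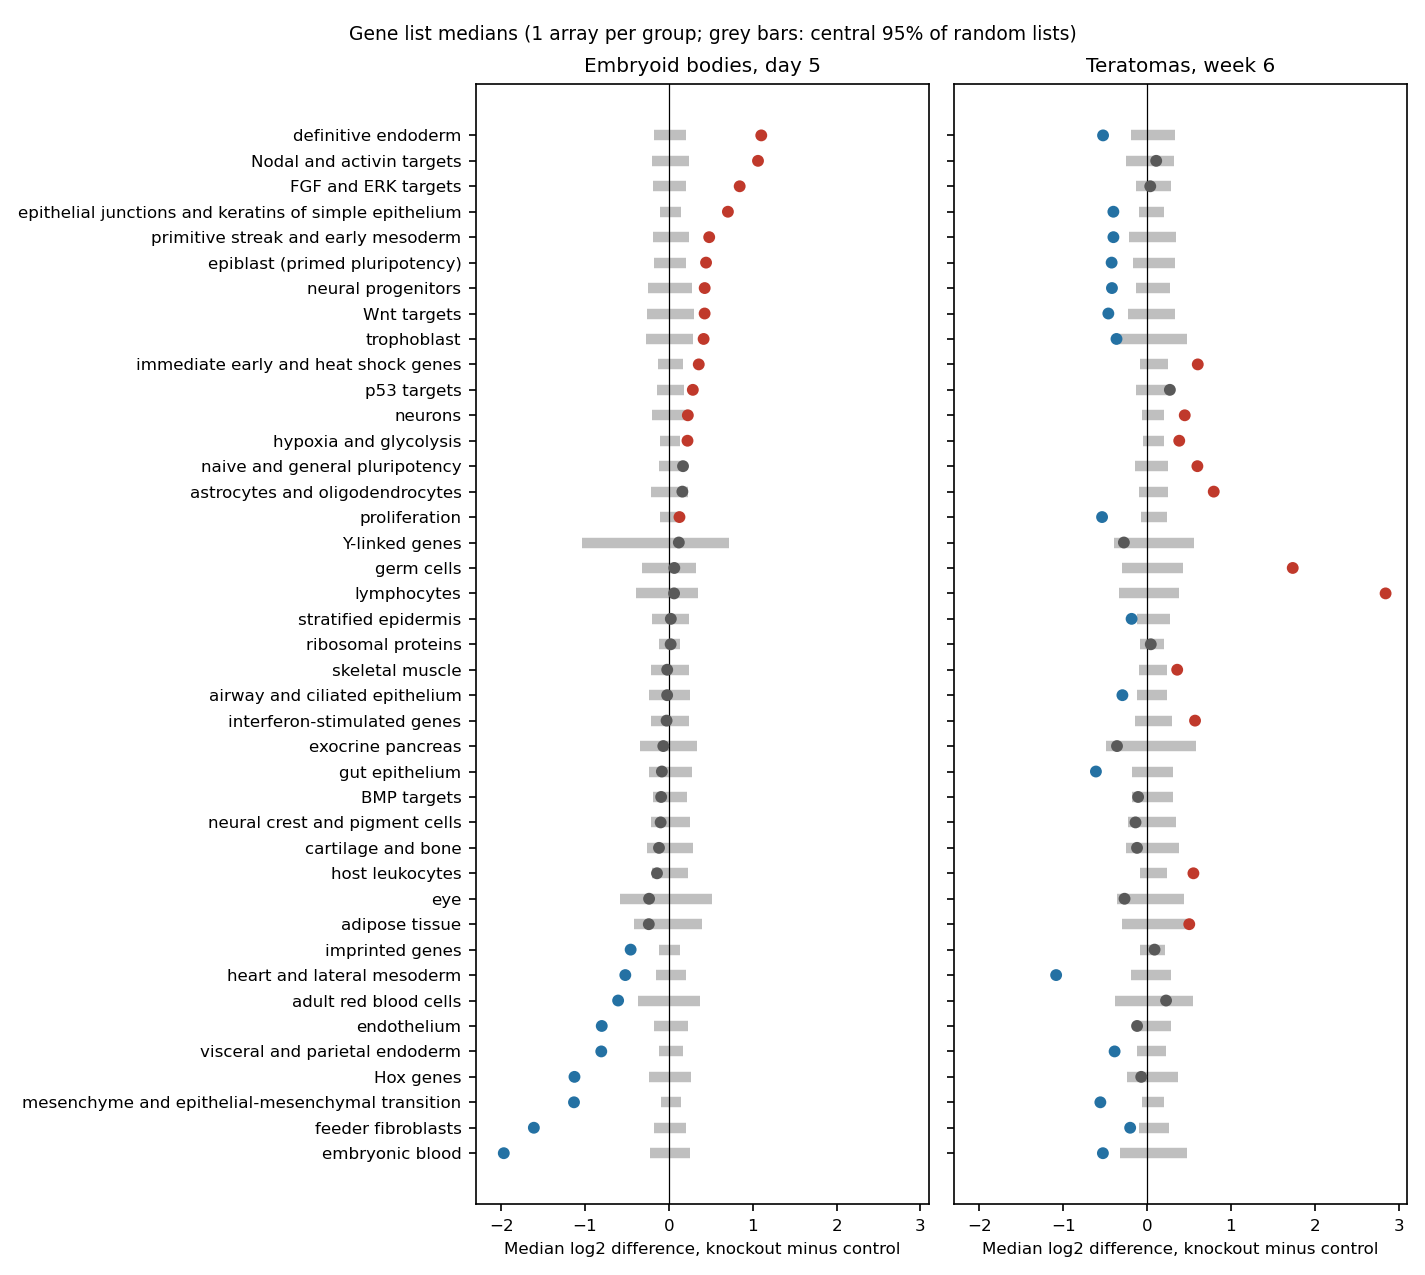
Each point is the median log2 difference, knockout minus control, of the measured members of a gene list in embryoid bodies (left) and teratomas (right). Grey bars span the central 95% of medians of random lists, red and blue points lie above or below that range, and embryonic blood is lowest in embryoid bodies (-1.97) while lymphocytes are highest in teratomas (2.84).

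The second comparison asked what differs in week 6 teratomas. The medians of the lymphocyte, leukocyte, neuronal, glial, pluripotency, germ cell, hypoxia and interferon lists lay above the central 95% of random lists. Those of the gut epithelium, heart, mesenchymal, neural progenitor and proliferation lists lay below it, in the last with no member lower by 2-fold. The immunoglobulin heavy chain gene Ighm was 70.6-fold higher, at 11.25 against 5.11, and the stomach gastrokine genes Gkn1 and Gkn2 were both 8.15-fold lower. Of 12197 measured genes, 397 were at least 2-fold higher and 131 at least 2-fold lower, the reverse of the balance in embryoid bodies. At 8-fold the counts were 5 higher and 3 lower. Other probe sets had the same sign for 114 of 126 higher and 48 of 49 lower genes, with a pooled SD between probe sets of 0.29. Teratomas are mixed tissue, and whether each RNA came from 1 tumour or several is not stated, so cellular makeup and genotype cannot be separated here.

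Lymphocyte genes had the highest median of any list, 2.84 over 5 measured members of 14, with 3 higher. The antibody joining chain gene Jchain and the B-cell surface gene Ms4a1 were above the floor only in the knockout, at least 8.11-fold and at least 7.18-fold higher, as was the light chain segment Igkv8-30, at least 7.92-fold. Ighm was measured by 2 of its 11 probe sets, which differed by 4.32 and 6.14, and it lay below the floor on both arrays when probe sets were averaged or shared-sequence ones left out. With the floor at the 25th percentile the list's median was 0.12, at percentile 93.1. Leukocyte genes had a median of 0.55, with 7 of 27 higher and 0 lower. The neutrophil gene S100a8 was at least 7.43-fold higher, the protease gene Ctss 5.44-fold and the leukocyte antigen gene Ptprc 4.34-fold, the last through 1 of its 2 probe sets, which has a shared sequence. Lcn2, an acute-phase gene of neutrophils and epithelia, was 11.2-fold higher. Interferon-stimulated genes had a median of 0.57, with 2 of 17 higher, Ifit3 at 1.69 and Cxcl10 at 1.05.

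Neuronal genes had a median of 0.45, with 9 of 27 higher and 1 lower. The GABA synthesis gene Gad2 differed by 2.42, the synaptic vesicle gene Syp by 1.86 and Cplx1 by 1.60, whereas the motor neuron and heart progenitor gene Isl1 differed by -1.51. Glial genes had a median of 0.80, with 5 of 17 higher, including the myelin gene Mobp at 2.18, the astrocyte filament gene Gfap at 1.44 and S100b at 1.37. The glycine receptor gene Glrb (2.65) and the neuropeptide gene Npy (2.59) were among the highest genes measured on both arrays. Fam107a differed by 3.73, with its probe sets ranging from -0.04 to 3.73. Neural progenitor genes had a median of -0.42, with 15 of 17 below 0, and the proneural gene Neurog2 differed by -1.46. The knockout teratoma also had the smaller 3' to 5' difference, 0.85 against 1.03 for Actb.

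Naive and general pluripotency genes had a median of 0.60, with 8 of 20 higher and 0 lower. Dppa3 and Dppa2 were above the floor only in the knockout, at least 4.41-fold and at least 4.14-fold higher, and Dppa4 and Tdgf1 were 3.06-fold and 3.04-fold higher. Dppa2 lay below the floor on both arrays without its shared-sequence probe set. Pou5f1 and Nanog, core pluripotency factors named after their values were seen, differed by 1.31 and 1.53. Germ cell genes had a median of 1.74 over 6 measured members of 15, with 4 higher: Dppa3, Rhox5 at 2.01, the RNA-binding protein gene Dazl at 1.89 and the meiosis gene Stra8 at 1.58. Epiblast genes, in contrast, had a median of -0.42, with Tead2 at -1.06.

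Hypoxia and glycolysis genes had a median of 0.38 with all 26 members above 0, and Car9 (1.38), Adm (1.26) and Aldoc (1.01) were at least 2-fold higher. Immediate early and heat shock genes had a median of 0.60, with 5 of 21 higher, including the chaperone genes Hspa1a at 1.53 and Hspa1b at 1.15. Proliferation genes had a median of -0.54, with 24 of 26 below 0 but 0 lower by 2-fold. Mki67 differed by -0.97 and Nusap1 by -0.90.

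Gut epithelium genes had a median of -0.61, with 5 of 13 lower and 0 higher. Besides Gkn1 and Gkn2, the trefoil factor gene Tff1 was 3.55-fold lower, Tspan8 2.67-fold lower and Gkn3, outside the list, at least 4.27-fold lower. The antimicrobial lectin gene Reg3b was 8.78-fold lower. Airway genes had a median of -0.29, with the secretory gene Scgb3a2 at -1.82 but Scgb1a1 at 1.25. Visceral and parietal endoderm genes had a median of -0.39, with 6 of 20 lower and 1 higher. Afp was 7.14-fold lower and the pepsinogen gene Pga5 5.22-fold lower, while transthyretin, Ttr, was 5.85-fold higher. Definitive endoderm genes had a median of -0.52, with Sox17 at -1.42 and Tmprss2 at -1.10. The epithelial list had a median of -0.40, with 28 of 34 members below 0 and 1, Krt8 at -1.02, lower by 2-fold. Cdh1 differed by -0.44.

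Heart genes had a median of -1.08, with 7 of 13 lower and 0 higher. Atrial myosin light chain Myl7 was at least 7.02-fold lower, Actc1 6.29-fold lower and Myh6 at least 3.48-fold lower. Mesenchymal genes had a median of -0.56, with 9 of 31 lower and 2 higher. Smooth muscle actin Acta2 differed by -1.53 through 1 of its 3 probe sets, the crosslinking enzyme gene Lox by -1.37, and the fibroblast activation gene Fap was at least 3.85-fold lower, whereas S100a4, also made by leukocytes, differed by 1.71. Smooth muscle Actg2 was 6.47-fold lower. Skeletal muscle genes went both ways, with 4 of 23 higher and 5 lower. The myosin gene Myh2 was at least 12.1-fold higher and myoglobin, Mb, 6.07-fold higher. The myosin genes Myh3 and Myh4 were 4.25-fold and at least 5.41-fold lower. The list's median of 0.36 turned to -0.035 with the floor at the 25th percentile. Nrk was 6.51-fold lower, the chemokine gene Ccl8 5.64-fold lower and the endothelial gene Esm1 6.09-fold higher.

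The lists that remained at the low end were primitive streak with a median of -0.40, embryonic blood with -0.53 over 4 measured members, Wnt targets with -0.46 (Dkk1 -1.38, Nkd1 -1.09) and epidermis with -0.18. Primitive streak stood at percentile 3.15 with the 65th percentile floor and epidermis at 17.1 with no floor. Trophoblast had -0.36 over 4 members, at percentile 1.92 and at 5.35 with the 65th percentile floor. The fibroblast list had -0.20, with 3 of 14 higher and 2 lower, and its mean stood at percentile 7.07. At the high end, adipose genes had a median of 0.50 at percentile 97.9, but 0.035 at percentile 52.1 with the mean of probe sets. The lipid carrier gene Fabp4 was 7.80-fold higher through 1 of its 4 probe sets, which has a shared sequence.

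In teratomas the other medians lay within the central 95% of random lists. They were -0.12 for endothelium, 0.23 for adult red blood cells, -0.12 for cartilage and bone, -0.36 for exocrine pancreas, -0.14 for neural crest and -0.27 for eye. Nodal and activin targets had 0.11, BMP targets -0.11, FGF and ERK targets 0.04, Hox genes -0.07, imprinted genes 0.09, p53 targets 0.27, Y-linked genes -0.28 and ribosomal protein genes 0.04. The medians of FGF and ERK targets, imprinted genes and ribosomal protein genes changed sign under some scalings, and the Hox mean was positive. Anxa10, at least 3.56-fold lower, completes the genes measured on 1 array only. With the mean of probe sets Nrk differed by -0.47, and Afp, Syp, Mobp, Lox, Krt8, Tspan8, Tmprss2, Myh4, Nkd1, Dkk1, Anxa10 and Snai2 were under 2-fold. Without shared-sequence probe sets Gkn3 and Tspan8 were under 2-fold and Anxa10 lay below the floor on both arrays. With the floor at the 65th percentile Dppa2, Dppa3, Dppa4, Dazl, Car9, Cxcl10, Neurog2, Sox17, Tmprss2, Fap, Gkn3, Myh6, Dkk1 and Anxa10 were under 2-fold. Scgb1a1 lay below that floor on both arrays. Under every scaling Aldoc was under 2-fold.

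**Figure D2:**
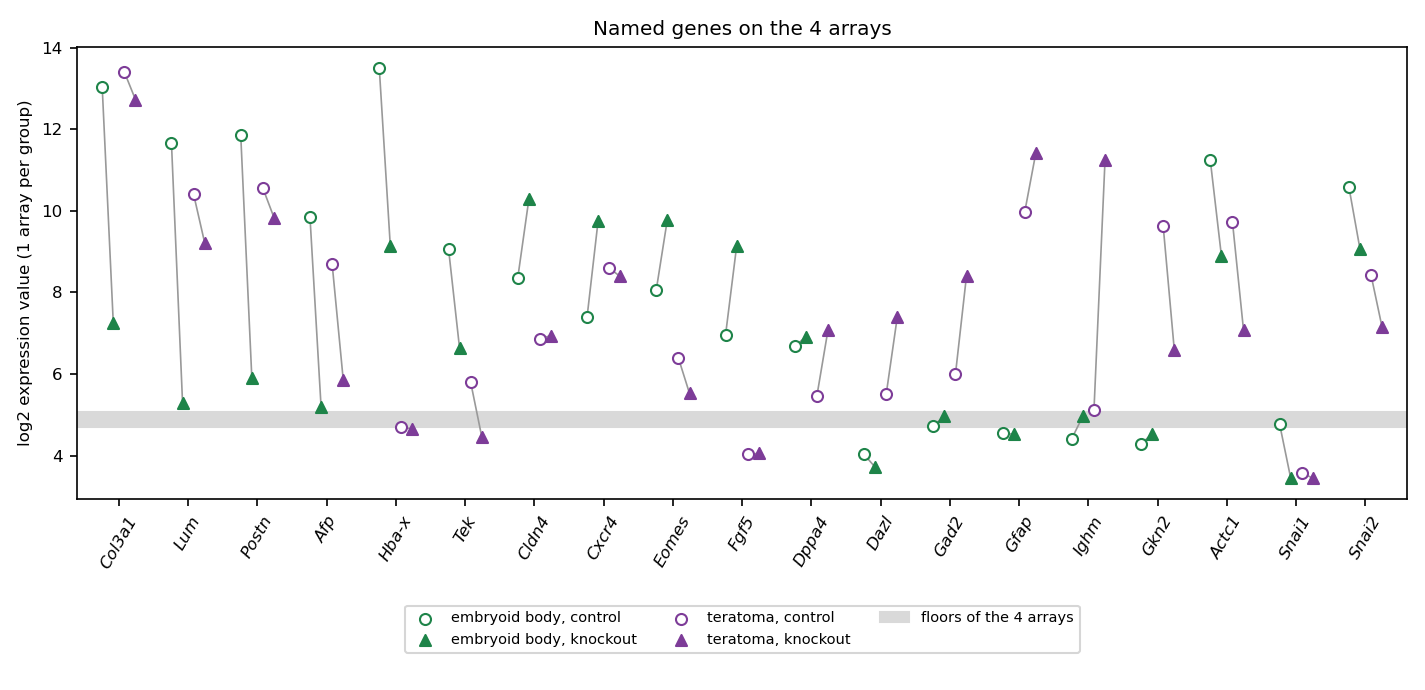
Log2 expression values of genes chosen from those named in the text, on each of the 4 arrays, with circles for control and triangles for knockout and a grey band for the floors of the arrays (4.71 to 5.08). Grey lines join control and knockout of the same tissue, and Snai1 lies within or below the band on all 4 arrays.

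Another question is whether the knockout differences were shared between embryoid bodies and teratomas. Smooth muscle and cardiac actins and alpha-fetoprotein were lower in both knockouts, but across genes the differences were almost unrelated. Over 11187 genes measured in both, Pearson's r was 0.02 and Spearman's rho -0.06. The 2 comparisons share no array, and genes are not independent replicates. There were 26 genes at least 2-fold lower in both, against 3.36 if the lists were independent, and 12 higher in both, against 4.56. In opposite directions, 16 genes were lower in embryoid bodies and higher in teratomas, against 8.56, and 5 were higher in embryoid bodies and lower in teratomas, against 1.79.

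Among genes lower in both, Afp differed by -4.64 in embryoid bodies and -2.84 in teratomas and Actc1 by -2.34 and -2.65. Actg2 was at least 4.23-fold lower in embryoid bodies and 6.47-fold lower in teratomas. Mbnl3, a splicing regulator gene, differed by -2.43 and -1.59 and Acta2 by -2.34 and -1.53. Myh6 was at least 4.78-fold and at least 3.48-fold lower. Of genes with opposite signs, the protease inhibitor gene Ctla2a differed by -2.40 in embryoid bodies and 2.03 in teratomas, Ttr by -1.72 and 2.55 and the chaperone gene Cryab by -1.98 and 1.37. The phosphatase gene Acp5 was at least 5.34-fold lower in embryoid bodies and at least 3.03-fold higher in teratomas. Isl1 differed by 1.57 and -1.51 and the Wnt inhibitor gene Dkk1 by 1.47 and -1.38. Without shared-sequence probe sets, Acta2 and Cryab lay below the floor on all arrays. With the mean of probe sets, Myh6 differed by -0.25 in embryoid bodies and lay below the floor in teratomas, and Dkk1 differed by -0.11 in teratomas. Afp, Mbnl3, Actg2 and Acp5 were under 2-fold in at least 1 tissue under some alternative. Lists at the low end in both tissues included mesenchyme, heart, visceral endoderm and embryonic blood. In teratomas, however, 0 of the 4 measured embryonic blood members were lower by 2-fold.

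**Figure D3:**
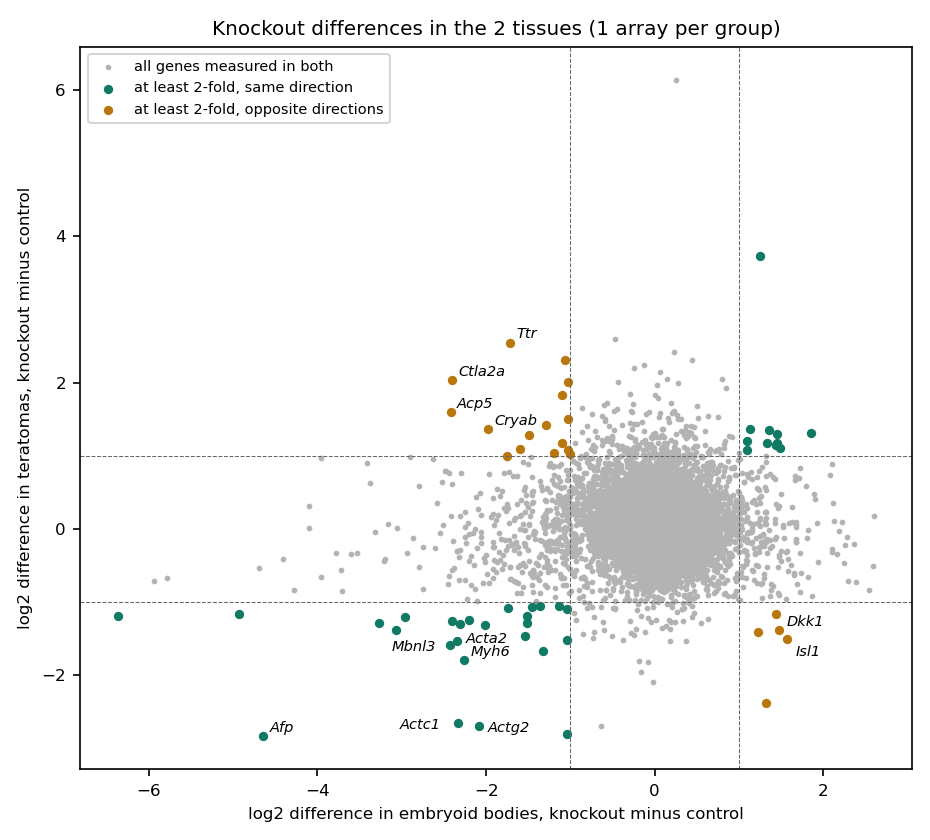
Each point is a gene measured in both tissues, with its log2 difference (knockout minus control) in embryoid bodies on the horizontal axis and in teratomas on the vertical axis. Dashed lines mark 2-fold, coloured points are at least 2-fold in both, and the 26 genes lower in both form the group at the lower left.

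The last comparison set teratomas against embryoid bodies within each genotype. The medians of the neuronal, glial, skeletal muscle, epidermal and leukocyte lists were higher in teratomas of both genotypes, and those of the proliferation, embryonic blood and extraembryonic endoderm lists were lower. In the control, 2098 genes were at least 2-fold higher in the teratoma and 2456 lower, and in the knockout 2566 higher and 2564 lower. Of these, 1786 were higher and 1751 lower in both genotypes. Neuronal genes had a median difference of 4.65 in the control and 5.04 in the knockout, glial genes 3.08 and 4.16, skeletal muscle genes 2.76 and 3.01, epidermal genes 1.99 and 1.78, and leukocyte genes 2.22 and 2.79. Proliferation genes had medians of -1.60 and -2.07 and embryonic blood genes -2.72 and -1.39. Mesenchymal genes had 0.29 in the control and 1.16 in the knockout, epithelial genes -0.94 and -2.25, and naive pluripotency genes -1.18 and -0.11. Tissue, duration, host and RNA extraction differ together, and the balance of higher and lower genes depended on the scaling. Loess of each pair of arrays gave 2594 higher and 1464 lower in the control and 3077 and 1639 in the knockout, and median centring gave 2490 and 1836 in the control and 2860 and 2046 in the knockout.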

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

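Results in which the 2 knockout comparisons pointed in opposite directions are collected here by a fixed rule, together with signals on probe sets outside the main measurement. With 1 array per group none of these differences between tissues was tested. Each value is the knockout difference in embryoid bodies minus that in teratomas, on the log2 scale.

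In 8 gene lists the median lay above the central 95% of random lists in embryoid bodies and below it in teratomas. Definitive endoderm differed most between tissues, by 1.63 (1.10 against -0.52). The epithelial list differed by 1.11 (0.70 against -0.40). Wnt targets differed by 0.89, primitive streak genes by 0.88, epiblast genes by 0.87 and neural progenitor genes by 0.85. Trophoblast genes differed by 0.78 and proliferation genes by 0.66. The embryoid body calls for primitive streak, trophoblast, Wnt targets and proliferation, and the teratoma calls for primitive streak and trophoblast, were lost under some alternatives.

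Among named genes, 9 differed at least 2-fold in opposite directions. Lower in embryoid bodies and higher in teratomas were Ctla2a (-4.43 between tissues), Ttr (-4.27), Cryab (-3.35) and Rhox5 (-3.04), and Acp5, whose value of -4.02 is a bound because it lay below the floor on 1 array in each tissue. Higher in embryoid bodies and lower in teratomas were Pga5 (3.70), Isl1 (3.08), Dkk1 (2.85) and Sox17 (2.65). Sox17, an endoderm regulator gene, differed by 1.23 in embryoid bodies and -1.42 in teratomas. The embryoid body values of Sox17 and Pga5 were chosen after the values were seen.

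Of the array control probe sets for the phage recombinase Cre, AFFX-CreX-3_at and AFFX-r2-P1-cre-3_at lay above the floor in both knockouts and read higher there than in the matching control, while AFFX-CreX-5_at and AFFX-r2-P1-cre-5_at lay below the floor in the knockout embryoid bodies. AFFX-r2-P1-cre-3_at differed by 1.08 in embryoid bodies before the floor was applied and by at least 0.88, under 2-fold, with it, and by 0.51 in teratomas. AFFX-CreX-3_at was higher by 0.65 and 0.24, and lay above the floor in both controls as well, at 5.44 and 6.00. On AFFX-r2-P1-cre-3_at the control embryoid bodies read 4.51, below the floor, and the control teratoma 6.37, above it. The bacterial controls lay below the floor on all arrays, for example AFFX-BioC-3_at at 3.26 and 3.29 in embryoid bodies, except AFFX-BioDn-3_at, which read 6.24 and 6.28 there. The labels say nothing of Cre or of spiked control RNA.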

How the results depend on the processing

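Requiring all of 2 or more probe sets of a gene to differ by 2-fold was added after the data were seen. The other alternatives were set before the data were examined. No paired analysis, with control and knockout paired within each tissue, was run, and no result comes from a test. Leaving out replicates was impossible because each group has 1 array.

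Counts of 2-fold genes, given as higher and lower in embryoid bodies and then in teratomas, moved with the threshold and the floor by construction. They were 850, 1024, 1256 and 616 at 1.5-fold and 63, 213, 83 and 27 at 3-fold. With the floor at the 65th percentile they were 169, 310, 262 and 76, and with all of 2 or more probe sets 34, 81, 42 and 20. The latter are out of the 87, 205, 126 and 49 2-fold genes that had another measured probe set. The mean of probe sets gave 86 lower in teratomas, and the cause was not tested. Under the remaining alternatives they ranged over 224 to 316, 345 to 566, 266 to 451 and 107 to 187. Lists at the high and low ends numbered 10 to 15 and 9 to 11 in embryoid bodies and 9 to 12 and 14 to 18 in teratomas.

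Overlaps are given as higher in both, lower in both, embryoid bodies higher with teratomas lower, and the reverse. They were 102, 114, 69 and 137 at 1.5-fold, 0, 5, 0 and 3 at 3-fold and 6, 15, 3 and 8 with the 65th percentile floor. The mean of probe sets gave 16 lower in both. Genes higher in embryoid bodies and lower in teratomas numbered 9 with the 25th percentile floor, 9 with no floor and 8 after quantile normalization. Spearman's rho was -0.083 with the 65th percentile floor and -0.045 with none. The causes of these moves were not tested.

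For teratoma against embryoid body, the 3-fold threshold gave 1307 higher and 906 lower in the control and 1687 and 1047 in the knockout. At 1.5-fold, 4324 were lower in the control and 4295 in the knockout. Loess gave 1464 and 1639 lower, and the cause was not tested.

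Of the list medians that stood apart, 2 changed sign. Skeletal muscle in teratomas was -0.035 with the 25th percentile floor and -0.035 with no floor, and adipose tissue in teratomas was -0.041 with no floor, and the cause was not tested. Ttn in embryoid bodies differed by -2.11 and by 0.040 without shared-sequence probe sets, which left another probe set. Of 198 named differences of at least 2-fold, 1 was reversed, 22 lay below the floor on both arrays under some alternative, and 175 kept their direction under every alternative. In total 81 were under 2-fold in some. Signal over background is the limit: the floor sets every bound, and genes below it on both arrays have no difference.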

Other observations

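The tests of host B cells, a lymph node and undifferentiated stem cells were written before their result was seen, and those of normalization and of feeder fibroblasts only after the result was seen. Genes and lists in this part were chosen after the main values were seen.

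Further cell type genes gave these values in the knockout teratoma against the control. The endoplasmic reticulum gene Mzb1, typical of antibody-secreting cells, was above the floor only in the knockout, at 6.12, while other genes of such cells did not differ by 2-fold (Xbp1 0.12, Prdm1 -0.44, Sdc1 -0.31, Derl3 0.28 and Fkbp11 0.018) or lay below the floor on both arrays (Irf4, Tnfrsf17 and Pou2af1). Of genes shared by embryonic stem cells, Fbxo15 differed by at least 2.05, L1td1 by 1.46 and Ooep by 1.25. Xist, the X-inactivation transcript, read 5.03 and 5.51 in control and knockout embryoid bodies and 7.32 and 8.12 in control and knockout teratomas. The Y-linked gene Eif2s3y read 8.02, 8.02, 7.70 and 7.63 in the same order.

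Collagen and mesenchymal transcripts were lower in knockout embryoid bodies, together with primitive blood and visceral endoderm. Random lists of matched expression reached a median of only -0.10 against -1.13 for the mesenchymal list. After loess, and after quantile normalization, 17 of its members were at least 2-fold lower, as without them. These scalings moved differences in embryoid bodies by at most 0.083 and 0.098, so the count could hardly change. Little trend with expression level was thus left between the 2 arrays. What the authors' own normalization did to the values cannot be told from this. The list was singled out because it lay outside these same random lists, so they are not a separate test. Feeder fibroblasts left in the control remain open for the mesenchymal part, while the labels name no feeder layer. Fibroblast genes outside the mesenchymal list had a median of -0.94 over 6 members. In control embryoid bodies 13 of the 15 fibroblast list genes on the array were above the floor, as were 32 of 34 mesenchymal list genes. That count cannot tell feeder fibroblasts from mesenchymal cells of the embryoid bodies themselves. For primitive blood the feeder explanation was not decided, because the only value set against it was the list's own median of -1.97. An effect of the genotype on these lineages stays open and untested, since 1 array per group cannot separate it from variation between cultures.

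Immunoglobulin and B-cell transcripts were higher in the knockout teratoma. Host B cells in the sampled tissue are a candidate source, because nude mice lack a normal thymus but have B cells. Further B-cell genes had a median of 0.74 over 6 measured of 19, with Cd52 at 2.01 and Cd22 at least 1.26 but Ly6d at 0.18. Cd74, at 1.04, is among these 6 and is also in the leukocyte list described above. Without Cd74 the middle value is that of Blnk, 0.44, which is under the bound set against host B cells. Blnk, however, also read 5.71 in control embryoid bodies, which have no host, and 5.80 in the control teratoma. Its level therefore does not report host B cells alone. The median thus depends on a reused gene and on Blnk, and host B cells are neither shown nor excluded. A lymph node taken with the tumour could not be judged, since 0 of 7 lymph node stroma genes reached the floor. Whether this reflects the genotype or the piece of tissue sampled was not tested.

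Pluripotency and germ cell transcripts were higher in the knockout teratoma, although the medians of the epiblast and proliferation lists were below 0 (-0.42 and -0.54). Random lists of matched expression reached 0.25 against 0.60 for the pluripotency list. After loess, and after quantile normalization, 8 of its members were at least 2-fold higher, as without them. These scalings moved differences in teratomas by at most 0.091 and 0.140, so here too the count could hardly change. Little trend with expression level was left between the 2 teratoma arrays. What the authors' own normalization did to the values cannot be told from this. This list too was singled out because it lay outside these same random lists, so they are not a separate test. A larger remnant of undifferentiated or germ cells may explain the pattern: further stem cell genes had a median of 0.55 over 11 measured members, with 5 at least 2-fold higher and 0 lower, which lies between the bounds set for and against it. Grhl2 (-0.74) and Spry4 (-0.14) were left out of that median because they are in the epithelial and FGF target lists. With both included, the middle value is that of Trim71, 0.48, which also lies between the bounds. Cd74, by contrast, was kept in the B-cell median although it is in the leukocyte list. A genotype effect on stem cell persistence stays open and untested, with 1 array per genotype.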
